A study of Homo sapiens with 60 samples.

How the data were processed

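RNA was measured on 60 arrays: HB4a, C5.2 and SKBR3 cells given vehicle, doxorubicin, rapamycin or both, 5 arrays per group. The values are log2 probe set summaries that the authors made with RMA, the only tool their notes name, with no version. Base 2 was inferred from the range, -0.60 to 13.08. The floor lies lower than RMA usually gives, and whether 1 RMA run covered all arrays is not stated. Labels give no scan dates, batches or detection calls, so line and any processing batch cannot be told apart. The labels call the vehicle group DRC, a name that the treatment text uses for the drug pair. The group was read as vehicle because the source names give DMSO for it. Doses were read as nM, as in the source names, where the treatment text has hM.
There were 54675 probe sets with values. Symbols came from the platform's annotation, updated by gene identifier. Of the probe sets, 41091 probe sets carried 1 symbol, 1801 with several symbols, 11777 unnamed here and 6 actin and GAPDH controls were left out, and some genes were not analysed here. Each of the 19775 genes was represented by its brightest probe set over all arrays. Names were used without coordinates. A gene was tested where its log2 value passed 5 on at least 5 arrays of the fit. MTOR did not pass.
Differences were tested with limma 3.58.1 in R 4.3.3 (linear fit, empirical Bayes with trend, 2-sided, Benjamini-Hochberg adjusted p under 0.05 over all genes tested). Within a line the fit held its 20 arrays, and between HB4a and another line 40. The contrasts were each treatment against vehicle, both drugs against each drug, the departure of both drugs from the sum of the single effects, the lines in vehicle, and the difference between lines in each response. Tables and plots used version 1.17.8 of data.table, Python 3.11.15 with pandas 2.3.3, numpy 2.4.6 and matplotlib 3.10.9.
The 23 gene lists were written before the data were examined, as were the filter, the tests and the rule for naming genes. They were p53 targets, G2 and mitosis, DNA replication, homologous recombination, histone genes, cholesterol synthesis, fatty acid synthesis, glycolysis, hypoxia targets, pentose phosphate, ATF4 targets, ribosome biogenesis, lysosome, oxidative phosphorylation, FOXO targets, ERK output, type I interferon response, NF-kB targets, mesenchymal, luminal and basal markers, ERBB2 neighbours on 17q12, and leukocyte and endothelial markers. Of their 488 genes 438 had a value. Lists were tested with camera (preset correlation 0.01), again with an estimated correlation, and with fry. Adjustment was over the lists of a contrast.
Named genes were, for a treatment against vehicle, the 5 largest rises and falls among called genes whose groups did not overlap, and the 3 largest for other contrasts. Added were up to 2 changed members in each direction of a called list or a list with 3 or more changed members, and always ERBB2, CDKN1A, MDM2, TOP2A, MTOR, IRS2 and EGFR.
The same experiment numbers occur in every group. Arrays of equal number were taken as paired where every pair's residuals correlated above 0.1. This held for all SKBR3 comparisons (lowest 0.238), for HB4a without the combined group and for C5.2 except vehicle against combined. It did not hold for HB4a with the combined group (lowest -0.569). Counts with the number as a block stand beside those comparisons where pairing held.
Alternatives were no filter, a filter at log2 7, the mean of all probe sets, array centring, quantile normalization, no trend, array weights, the block, only the arrays compared, all 60 arrays in 1 fit, and each array left out in turn. Chosen after the data were seen were a filter at log2 3, leaving out arrays that stood apart (HB4a number 1 and rapamycin 4, C5.2 number 2, SKBR3 number 1), a random block for the lines in vehicle, the block with only the arrays compared, and lists without SKBR3 vehicle array 3. Other splits of the arrays, at most 100 per result, were counted with a fixed seed.
On simulated data 86.6% of HB4a genes moved by 1 log2 unit were recovered and 38.8% at 0.5. Such data lack shared experiment effects, so 0 calls in 380 unmoved-list tests say little.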

Results

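RNA levels were measured with 60 Affymetrix expression arrays (the U133 Plus version 2 design) in 3 human breast cell lines, each under 4 conditions. HB4a is a line of normal breast epithelial cells. C5.2 was made from HB4a by transfer of a cDNA for the growth factor receptor HER-2, encoded by ERBB2. SKBR3 came from a mammary adenocarcinoma that overexpresses HER-2. Cells received the DMSO vehicle, doxorubicin at 30 nM, rapamycin at 20 nM, or both drugs. Doxorubicin is an anthracycline that traps topoisomerase II on DNA, and rapamycin inhibits the kinase complex mTORC1. The labels used here give no treatment time. Each of the 12 groups held 5 arrays from independent experiments, and this number limits the precision. Array medians lay between 1.41 and 1.71 log2 units. The stated purpose was the expression response of HER-2-overexpressing mammary lines to the drug pair, so each treatment was set against its line's vehicle, the pair against each drug, and the lines against each other. Changes are differences of group means in log2 units ± the standard error from limma, with n = 5 arrays per group, and a gene rose or fell where its 2-sided adjusted p was under 0.05 in the fit without pairing. For a gene list, the camera test asks whether its members moved beyond the other genes, and counts are out of the members past the filter. Where at least 2 of a group's arrays lay at or under their array medians, taken as background, a difference is given as "at least", a lower bound from those medians.
ERBB2 itself averaged 6.67 (SD 0.23) in vehicle-treated HB4a, 12.06 (SD 0.25) in C5.2 and 11.48 (SD 0.35) in SKBR3 (n = 5 arrays each). It was 5.38 ± 0.14 higher in C5.2 and 4.81 ± 0.17 higher in SKBR3 than in HB4a, with adjusted p = 1.41e-28 and 2.38e-25. In that fit 0 of 9 treatments against vehicle called ERBB2. With the experiment number as a block, it was called up with doxorubicin in HB4a (0.28 ± 0.18 and adjusted p = 0.341 without the block, 0.0259 with it). So it was in SKBR3, where vehicle array 1 was low (10.87, others from 11.57), with rapamycin (0.21 ± 0.15, 0.366 and 0.0262) and both drugs (0.17 ± 0.15, 0.393 and 0.0492).

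**Figure D1:**
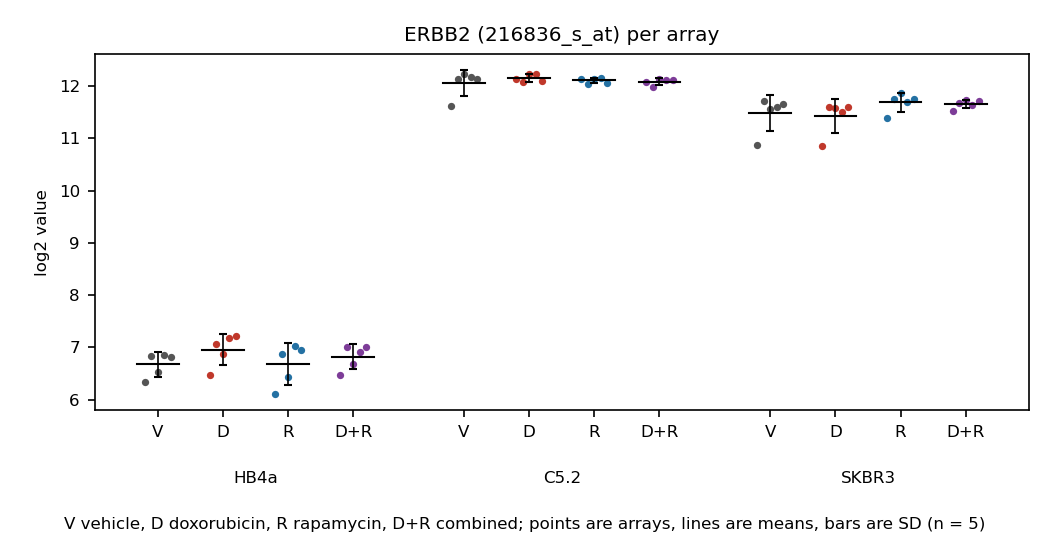
ERBB2 log2 value (vertical axis) on every array by line and treatment (horizontal axis), with points for arrays, lines for means and bars for SD (n = 5). All C5.2 and SKBR3 arrays lay above all HB4a arrays, at vehicle means of 12.06, 11.48 and 6.67.

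In vehicle, C5.2 differed from its parent HB4a beyond the added receptor. The collagen gene COL3A1 (8.16 ± 0.15), the LIM-domain gene CRIP1 (at least 7.24) and the matrix inhibitor of calcification MGP (at least 5.26) were among the most raised in C5.2. The collagen cross-linking enzyme LOX (-5.99 ± 0.26), the transcription cofactor VGLL1 (lower by at least 4.93) and COXFA4L3 (at least 5.16) were among the most lowered. Lower in C5.2 were also E-cadherin CDH1 (-3.70 ± 0.25), keratin KRT19 (-2.63 ± 0.24), P-cadherin CDH3 (-3.21 ± 0.18) and keratin KRT5 (-3.06 ± 0.23). The metabolic kinase PDK4 was at least 4.54 higher, while EGFR (-1.40 ± 0.13), cyclin CCND1 (-2.85 ± 0.33), the amino acid carrier SLC7A5 (-2.46 ± 0.14) and CDKN1A (-1.70 ± 0.19) were lower. In all 3425 of 6962 genes differed, 2043 higher and 1382 lower in C5.2, 973 of them by 2-fold or more. Camera called the luminal epithelial markers lower (1 of 11 higher and 9 lower, 1 and 9 adjusted over the list alone, median -1.19, camera adjusted p = 1.61e-05, adjusted p = 0.201 with an estimated correlation). The ATF4 targets were called lower too (0 of 23 higher and 13 lower, 0 and 14 adjusted over the list alone, median -0.28, camera adjusted p = 0.000959, adjusted p = 0.534 with an estimated correlation). So was glycolysis (3 of 20 higher and 10 lower, 4 and 11 adjusted over the list alone, median -0.25, camera adjusted p = 0.0182, adjusted p = 0.659 with an estimated correlation). Mesenchymal markers were called higher (8 of 11 higher and 1 lower, 8 and 1 adjusted over the list alone, median 0.76, camera adjusted p = 0.00229, adjusted p = 0.364 with an estimated correlation). None of these 4 calls held with an estimated correlation. The basal markers had no call (5 of 12 higher and 5 lower, 5 and 5 adjusted over the list alone, median 0.33, camera adjusted p = 0.178). Differences between lines also hold any difference between the batches in which their arrays were processed, which the labels do not give.
SKBR3 stood farther from HB4a. The secretoglobin SCGB2A2 (at least 9.26) and the cancer-testis genes MAGEA6 (at least 7.68) and MAGEA12 (at least 6.77) were among the most raised. The lectin LGALS3 (lower by at least 8.33), the methyltransferase NNMT (at least 7.92) and the matrix protein SPARC (at least 7.44) were among the most lowered. All 10 tested neighbours of ERBB2 on 17q12 were higher, led by the gasdermin GSDMB (7.45 ± 0.11) and the mediator subunit MED1 (4.84 ± 0.33). This list's call held (10 of 10 higher and 0 lower, 10 and 0 adjusted over the list alone, median 3.56, camera adjusted p = 5.25e-07). All 12 tested basal and myoepithelial markers were lower, KRT5 by at least 8.23 and CDH3 by at least 6.50. Their call held (0 of 12 higher and 12 lower, 0 and 12 adjusted over the list alone, median lower by at least 3.85, camera adjusted p = 1.24e-06). The mesenchymal markers were called lower (0 of 8 higher and 8 lower, 0 and 8 adjusted over the list alone, median lower by at least 5.60, camera adjusted p = 1.24e-06, adjusted p = 0.0518 with an estimated correlation). So were the p53 targets (2 of 22 higher and 17 lower, 2 and 17 adjusted over the list alone, median -1.10, camera adjusted p = 0.00222, adjusted p = 0.233 with an estimated correlation). Among these GDF15 stood at -3.88 ± 0.42 and TP53I3 at -4.15 ± 0.31, or -4.60 and -4.69 without SKBR3 vehicle array 3. The luminal markers were called higher (13 of 18 higher and 4 lower, 13 and 4 adjusted over the list alone, median 1.56, camera adjusted p = 0.00159, adjusted p = 0.233 with an estimated correlation). Histone genes were higher (5 of 5 higher and 0 lower, 5 and 0 adjusted over the list alone, median 2.02, camera adjusted p = 0.00665, adjusted p = 0.233 with an estimated correlation). Fatty acid synthesis was called higher (6 of 9 higher and 1 lower, 6 and 1 adjusted over the list alone, median 1.23, camera adjusted p = 0.018, adjusted p = 0.115 with an estimated correlation). IRS2, an insulin receptor adaptor, was lower by at least 5.78, and TOP2A, the target of doxorubicin, differed by 3.51 ± 0.39. Of 7270 genes 5618 differed, 2734 higher and 2884 lower. SKBR3 vehicle array 3 carried extra RNA: 9 genes high in HB4a and C5.2 and near the floor on the other SKBR3 arrays, among them LGALS3, NNMT and SPARC, stood a median 3.53 above the other 4 vehicle arrays there. Without it 5495 genes differed.
Doxorubicin in HB4a raised p53 targets. The secreted stress cytokine GDF15 rose by 2.77 ± 0.25 (6.83-fold, from 6.83 (SD 0.66) to 9.60 (SD 0.23), n = 5 arrays per group), the quinone reductase homologue TP53I3 by 2.13 ± 0.16 and the cell-cycle inhibitor CDKN1A by 1.75 ± 0.16. Outside that list the reductase AKR1B10 (2.44 ± 0.29), SUGCT (2.21 ± 0.13) and the adhesion molecule NECTIN4 (2.11 ± 0.19) rose most. The transcription factor FOXQ1 (-1.75 ± 0.26), the growth-arrest gene GAS1 (-1.53 ± 0.32), the helicase subunit MCM6 (-1.20 ± 0.16), the sodium channel subunit SCNN1G (-1.17 ± 0.16) and thrombospondin THBS1 (-1.10 ± 0.15) fell most, and MYC fell by 1.01 ± 0.14. MDM2, the p53 ubiquitin ligase, rose by 1.27 ± 0.34, a call lost without vehicle arrays 3 and 4 and doxorubicin array 6 (range 1.10 to 1.48). The p53 list held its call under every setting tried (18 of 22 rose and 0 fell, 21 and 0 adjusted over the list alone, median 0.97, camera adjusted p = 9.68e-22). Ribosome biogenesis lay below the other genes (0 of 23 rose and 2 fell, 0 and 2 adjusted over the list alone, median -0.30, camera adjusted p = 2.23e-06), a call that held. The serine protease PLAU (1.34 ± 0.20) and the adhesion molecule ICAM1 (0.95 ± 0.17) rose. Their list, the NF-kB targets, was called up (2 of 5 rose and 0 fell, 3 and 0 adjusted over the list alone, median 0.55, camera adjusted p = 0.00667, adjusted p = 0.273 with an estimated correlation), a call lost when the mean of all probe sets was used. The ubiquitin-like ISG15 rose by 1.09 ± 0.23. Its list, the interferon genes, was called up (4 of 5 rose and 0 fell, 5 and 0 adjusted over the list alone, median 0.79, camera adjusted p = 0.00187, adjusted p = 0.273 with an estimated correlation). The adaptors IRS1 (-0.93 ± 0.16) and IRS2 (-0.43 ± 0.11) fell. Their list, the FOXO targets, moved down (0 of 12 rose and 3 fell, 0 and 4 adjusted over the list alone, median -0.19, camera adjusted p = 0.00122, adjusted p = 0.167 with an estimated correlation). TOP2A (0.23 ± 0.44) and EGFR (-0.15 ± 0.12) were not called with or without a block. In all 705 of 6167 genes changed, 534 up and 171 down, 74 by 2-fold or more. The count was 455 without vehicle array 1, 466 without vehicle array 3, 444 without doxorubicin array 4 and 428 without doxorubicin array 6, and 2014 in a fit with the experiment number as a block.

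**Figure D2:**
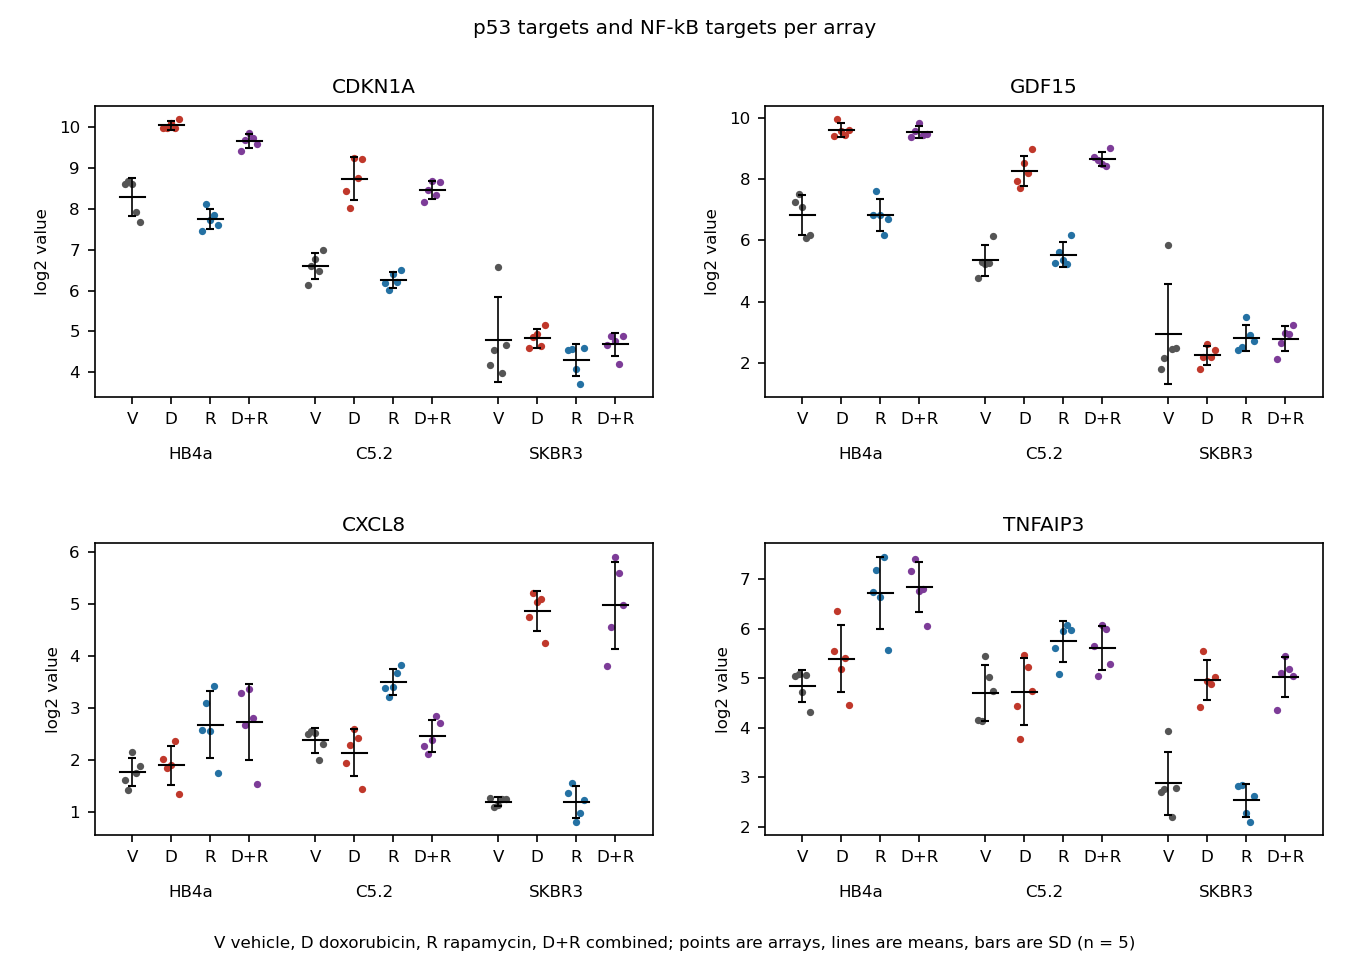
Log2 values (vertical axes) of the p53 targets CDKN1A and GDF15 and the NF-kB targets CXCL8 and TNFAIP3 on every array by line and treatment (horizontal axes), with points for arrays, lines for means and bars for SD (n = 5). In SKBR3, CXCL8 lay at or above 3.82 on arrays with doxorubicin and at or below 1.56 on arrays without.

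Rapamycin in HB4a gave upward calls of growth-signalling feedback lists and downward calls of sugar and lipid lists. The prostaglandin synthase PTGS2 (2.26 ± 0.32), the matricellular gene CCN2 (2.25 ± 0.25), the ERK phosphatase DUSP5 (1.90 ± 0.28), the cell-cycle regulator RGCC (1.90 ± 0.22) and the NF-kB inhibitor TNFAIP3 (1.88 ± 0.33) rose most. IRS2 rose by 1.20 ± 0.11 (2.29-fold) and EGFR by 0.55 ± 0.12. Keratins KRT15 (-1.45 ± 0.25) and KRT5 (-1.01 ± 0.13), the desaturase SCD (-1.05 ± 0.19), the stress-induced mTORC1 inhibitor DDIT4 (-1.04 ± 0.21) and the glycolytic enzymes PFKFB4 (-1.04 ± 0.20) and HK2 (-1.03 ± 0.11) fell. Of the glycolysis genes 0 of 19 rose and 10 fell, 0 and 13 adjusted over the list alone, median -0.32, camera adjusted p = 3.17e-16. The FOXO targets moved up (5 of 12 rose and 0 fell, 7 and 0 adjusted over the list alone, median 0.60, camera adjusted p = 1.76e-08). ERK output moved up (4 of 14 rose and 0 fell, 9 and 0 adjusted over the list alone, median 0.47, camera adjusted p = 6.97e-10). Fatty acid synthesis moved down (0 of 7 rose and 2 fell, 0 and 2 adjusted over the list alone, median -0.18, camera adjusted p = 0.00201). Cholesterol synthesis moved down (0 of 13 rose and 1 fell, 0 and 4 adjusted over the list alone, median -0.21, camera adjusted p = 0.000158). These 5 calls held. The cytokine IL6 rose by 1.56 ± 0.35, and its list, the NF-kB targets, moved up (3 of 5 rose and 0 fell, 4 and 0 adjusted over the list alone, median 0.46, camera adjusted p = 9.18e-06, adjusted p = 0.0536 with an estimated correlation). The ATF4 targets moved down (0 of 23 rose and 1 fell, 0 and 5 adjusted over the list alone, median -0.25, camera adjusted p = 5.80e-05, adjusted p = 0.182 with an estimated correlation). Mitotic genes moved up (0 of 24 rose and 0 fell, 8 and 0 adjusted over the list alone, median 0.20, camera adjusted p = 0.000562, adjusted p = 0.259 with an estimated correlation). TOP2A (1.14 ± 0.44) and CDKN1A (-0.55 ± 0.16) were called only with the block (adjusted p = 0.0259 and 0.0165). Of 6167 genes 196 changed, 128 up and 68 down, 36 by 2-fold or more, and 1008 changed with the experiment number as a block. The HB4a arrays numbered 1 and rapamycin array 4 stood apart, and without them 171 genes changed.
Both drugs together in HB4a gave calls of the p53 list and of metabolic lists. GDF15 (2.71 ± 0.25), the stress transcription factor ATF3 (2.70 ± 0.27), CCN2 (2.05 ± 0.25), TNFAIP3 (2.00 ± 0.33) and the actin regulator CYFIP2 (2.00 ± 0.18) rose most, and smooth muscle actin ACTA2 rose by 1.91 ± 0.17. CDKN1A rose by 1.36 ± 0.16 and MDM2 by 1.26 ± 0.34. DDIT4 (-2.08 ± 0.21), SCNN1G (-1.93 ± 0.16), HK2 (-1.71 ± 0.11), SCD (-1.65 ± 0.19) and KRT5 (-1.58 ± 0.13) fell most, and the luminal keratin KRT19 fell by 1.14 ± 0.16. The p53 list was called up (19 of 22 rose and 0 fell, 21 and 0 adjusted over the list alone, median 0.96, camera adjusted p = 1.55e-16). Ribosome biogenesis was called down (0 of 23 rose and 12 fell, 0 and 16 adjusted over the list alone, median -0.50, camera adjusted p = 3.31e-09). So was glycolysis (0 of 19 rose and 11 fell, 0 and 12 adjusted over the list alone, median -0.42, camera adjusted p = 6.10e-12). Fatty acid synthesis followed (0 of 7 rose and 3 fell, 0 and 3 adjusted over the list alone, median -0.22, camera adjusted p = 0.00301). These 4 calls held. All 5 NF-kB targets tested rose (5 of 5 rose and 0 fell, 5 and 0 adjusted over the list alone, median 1.64, camera adjusted p = 3.01e-06, adjusted p = 0.0524 with an estimated correlation). The hormone STC2 fell by 1.28 ± 0.13. Its list, the ATF4 targets, was called down (1 of 23 rose and 8 fell, 1 and 12 adjusted over the list alone, median -0.30, camera adjusted p = 1.32e-07, adjusted p = 0.0995 with an estimated correlation). The kinase CDK1 rose by 1.40 ± 0.26. Its list, G2 and mitosis, was called up (6 of 24 rose and 0 fell, 8 and 0 adjusted over the list alone, median 0.31, camera adjusted p = 0.0103, adjusted p = 0.33 with an estimated correlation), a call lost without the arrays that stood apart. In all 1074 of 6167 genes changed, 674 up and 400 down, 119 by 2-fold or more. Without the arrays that stood apart 1621 changed.
Doxorubicin in C5.2 gave a smaller set of changed genes than in HB4a, again led by p53 targets. GDF15 rose by 2.93 ± 0.24 (7.6-fold, from 5.35 (SD 0.50) to 8.27 (SD 0.50), n = 5), the adhesion molecule CEACAM1 by 2.58 ± 0.30, CDKN1A by 2.14 ± 0.20, CYFIP2 by 2.02 ± 0.28 and the stress gene SESN1 by 1.89 ± 0.21. The uracil glycosylase UNG (-0.88 ± 0.09) and MCM6 (-0.67 ± 0.14) fell. The homeobox gene IRX3, the mitochondrial gene COX3 and the drug exporter ABCG2 also fell, but each lost its call without at least 6 of the 10 arrays in turn, so no values are given. MDM2 rose by 1.51 ± 0.39, a call lost without vehicle arrays 1, 2, 3, 4 and 6 and doxorubicin arrays 3, 4 and 6 (range 1.29 to 1.84). The p53 list alone held its call (16 of 20 rose and 0 fell, 19 and 0 adjusted over the list alone, median 1.01, camera adjusted p = 2.88e-37). The mitotic genes UBE2C (0.59 ± 0.05) and KIF2C (0.56 ± 0.09) rose. G2 and mitosis was called up (3 of 25 rose and 0 fell, 5 and 0 adjusted over the list alone, median 0.19, camera adjusted p = 0.000454, adjusted p = 0.432 with an estimated correlation). DNA replication was called down (0 of 29 rose and 2 fell, 0 and 4 adjusted over the list alone, median -0.19, camera adjusted p = 9.91e-06, adjusted p = 0.308 with an estimated correlation). Ribosome biogenesis was called down (0 of 23 rose and 0 fell, 0 and 0 adjusted over the list alone, median -0.14, camera adjusted p = 0.000247, adjusted p = 0.308 with an estimated correlation). The 3 interferon genes tested were called up (0 of 3 rose and 0 fell, 3 and 0 adjusted over the list alone, median 0.39, camera adjusted p = 0.00625, adjusted p = 0.308 with an estimated correlation). TOP2A (0.06 ± 0.28) and IRS2 (0.20 ± 0.31) were not called. Of 6292 genes 205 changed, 179 up and 26 down, 23 by 2-fold or more. The count was 123 without vehicle array 1, 110 without vehicle array 3, 126 without vehicle array 4, 125 without vehicle array 6, 97 without doxorubicin array 3 and 108 without doxorubicin array 6, and 1093 with the experiment number as a block. Without the C5.2 arrays numbered 2, which stood apart, 561 changed.
Rapamycin in C5.2 lowered far more genes than it raised, though not among the 2-fold changes. The immediate-early gene EGR1 (1.99 ± 0.34), the ERK phosphatases DUSP6 (1.41 ± 0.22) and DUSP5 (1.20 ± 0.15), the EGFR inhibitor ERRFI1 (1.16 ± 0.27) and the factor MAFF (1.15 ± 0.10) rose most, and IRS2 rose by 1.28 ± 0.31. Neurofilament NEFL (-1.43 ± 0.18), the reductases AKR1B10 (-1.40 ± 0.25) and AKR1C2 (-0.99 ± 0.17), and DDIT4 (-1.02 ± 0.11) fell most. AKR1C1 fell 2-fold and KRT19 by 1.06 ± 0.28. The asparagine synthetase ASNS (-0.92 ± 0.11), PFKFB4 (-0.93 ± 0.16) and the thiolase ACAT2 (-0.69 ± 0.09) fell. Of the ATF4 targets, which supply amino acids, 0 of 22 rose and 14 fell, 0 and 16 adjusted over the list alone, median -0.40, camera adjusted p = 3.53e-07, adjusted p = 0.0604 with an estimated correlation. Of the glycolysis genes 0 of 17 rose and 10 fell, 0 and 13 adjusted over the list alone, median -0.38, camera adjusted p = 1.32e-06, adjusted p = 0.195 with an estimated correlation. Of the cholesterol genes 0 of 13 rose and 6 fell, 0 and 8 adjusted over the list alone, median -0.38, camera adjusted p = 0.000806, adjusted p = 0.0604 with an estimated correlation. ERK output moved up (7 of 14 rose and 0 fell, 7 and 0 adjusted over the list alone, median 0.34, camera adjusted p = 3.53e-07, adjusted p = 0.0604 with an estimated correlation). The FOXO targets moved up (3 of 12 rose and 0 fell, 3 and 0 adjusted over the list alone, median 0.60, camera adjusted p = 1.06e-06, adjusted p = 0.237 with an estimated correlation). Oxidative phosphorylation was called down (0 of 24 rose and 8 fell, 0 and 8 adjusted over the list alone, median -0.18, camera adjusted p = 0.021, adjusted p = 0.195 with an estimated correlation), a call lost without vehicle array 1 and with the mean of all probe sets. None of these calls held with an estimated correlation. Of 6292 genes 1097 changed, 178 up and 919 down, 24 by 2-fold or more (19 up and 5 down). The count was 644 without vehicle array 2, 704 without rapamycin array 3 and 686 without rapamycin array 4, and 2781 with the experiment number as a block.
Both drugs together in C5.2 raised every p53 target tested. GDF15 (3.30 ± 0.24, 9.88-fold), CEACAM1 (2.87 ± 0.30), EGR1 (2.80 ± 0.34), CYFIP2 (2.20 ± 0.28) and ATF3 (2.06 ± 0.25) rose most, with MDM2 at 2.02 ± 0.39 and CDKN1A at 1.87 ± 0.20. Keratins KRT13 (-3.54 ± 0.38), KRT5 (-1.94 ± 0.28) and KRT19 (-1.87 ± 0.28), the steroid reductase AKR1C3 (-1.55 ± 0.30) and the proteoglycan DCN (-1.54 ± 0.27) fell most. The p53 list held its call (20 of 20 rose and 0 fell, 20 and 0 adjusted over the list alone, median 1.05, camera adjusted p = 8.10e-26). UBE2C rose by 0.65 ± 0.05, MCM5 fell by 0.78 ± 0.16 and SCD by 1.41 ± 0.15. G2 and mitosis was called up (8 of 25 rose and 0 fell, 10 and 0 adjusted over the list alone, median 0.39, camera adjusted p = 4.37e-08, adjusted p = 0.131 with an estimated correlation). DNA replication was called down (1 of 29 rose and 12 fell, 1 and 16 adjusted over the list alone, median -0.32, camera adjusted p = 0.00295, adjusted p = 0.25 with an estimated correlation). Cholesterol synthesis was called down (0 of 13 rose and 7 fell, 0 and 8 adjusted over the list alone, median -0.52, camera adjusted p = 0.000395, adjusted p = 0.0627 with an estimated correlation). Glycolysis was called down (0 of 17 rose and 12 fell, 0 and 13 adjusted over the list alone, median -0.40, camera adjusted p = 1.81e-06, adjusted p = 0.131 with an estimated correlation). The ATF4 targets were called down (1 of 22 rose and 13 fell, 1 and 15 adjusted over the list alone, median -0.41, camera adjusted p = 1.81e-06, adjusted p = 0.0627 with an estimated correlation). The luminal markers were called down (0 of 10 rose and 5 fell, 0 and 6 adjusted over the list alone, median -0.51, camera adjusted p = 0.00461, adjusted p = 0.207 with an estimated correlation). In all 1320 of 6292 genes changed, 404 up and 916 down, 75 by 2-fold or more (42 up and 33 down).
Doxorubicin in SKBR3 changed few genes, led by inflammatory ones. The chemokine CXCL8 rose by at least 3.38, from background to 4.88 (SD 0.39) (n = 5), complement factor CFB by 2.41 ± 0.30, TNFAIP3 by 2.10 ± 0.28, the ciliary gene DNAAF1 by 1.91 ± 0.16 and the growth factor IGFL1 by 1.80 ± 0.21. The metallothionein MT2A (-0.61 ± 0.11) and TGFB3 (-0.51 ± 0.10) fell. The histone gene H2AC6 fell by 0.85 ± 0.19, a call lost without vehicle arrays 1 and 2 and doxorubicin arrays 3, 4 and 6 (range -0.95 to -0.78). All 3 NF-kB targets tested rose, also adjusted over the list alone (median 2.10, camera adjusted p = 9.22e-19), and this call held. CXCL8 and TNFAIP3 passed the filter only through arrays with doxorubicin, so the filter favoured this call and its p is no independent support. DNA replication lay above the other genes (0 of 28 rose and 0 fell, 14 and 0 adjusted over the list alone, median 0.28, camera adjusted p = 3.19e-13), which also held. None of the 11 p53 targets above the filter changed (0 of 11 rose and 0 fell, 0 and 0 adjusted over the list alone, median -0.03, camera adjusted p = 0.752). MDM2 (-0.16 ± 0.23), TOP2A (0.03 ± 0.29) and EGFR (0.28 ± 0.20) were not called. Of 5977 genes 50 changed, 40 up and 10 down, 17 by 2-fold or more. The count was 31 without doxorubicin arrays 3 and 4 in turn, 45 without vehicle array 3, and 299 with the block.
Rapamycin in SKBR3 lowered G2 and mitosis genes. The spindle gene DLGAP5 fell by 2.00 ± 0.31 (4-fold, from 5.41 (SD 0.54) to 3.41 (SD 0.64), n = 5), the mitotic kinase PBK by 1.81 ± 0.30, CEP55 by 1.78 ± 0.32, the kinetochore gene SPC25 by 1.75 ± 0.18, HMMR by 1.74 ± 0.31 and TOP2A by 1.41 ± 0.29. The cyclin CCNO (1.90 ± 0.17), the polyamine enzyme SAT1 (1.36 ± 0.10), keratin KRT23 (1.35 ± 0.23), RIPOR3 (1.34 ± 0.25) and the membrane gene EMP1 (1.34 ± 0.12) rose most. MCM10 fell by 1.66 ± 0.26, the serine enzyme PHGDH by 1.29 ± 0.13 and RAD51AP1 by 1.44 ± 0.29, and the glucose sensor TXNIP rose by 1.17 ± 0.13. All 24 G2 and mitosis genes fell, also adjusted over the list alone (median -1.40, camera adjusted p = 9.65e-26). DNA replication was called down (0 of 28 rose and 22 fell, 0 and 24 adjusted over the list alone, median -0.63, camera adjusted p = 2.96e-17). The FOXO targets moved up (5 of 7 rose and 0 fell, 7 and 0 adjusted over the list alone, median 0.57, camera adjusted p = 3.95e-05). These 3 calls held. Cholesterol synthesis was called down (0 of 13 rose and 8 fell, 0 and 8 adjusted over the list alone, median -0.48, camera adjusted p = 0.0003, adjusted p = 0.0549 with an estimated correlation). The ATF4 targets were called down (0 of 21 rose and 7 fell, 0 and 8 adjusted over the list alone, median -0.23, camera adjusted p = 0.00149, adjusted p = 0.0645 with an estimated correlation). Of the p53 targets 1 of 11 rose and 2 fell, 1 and 2 adjusted over the list alone, median -0.03, camera adjusted p = 0.845. Their median and their mean (0.01) differed in sign. EGFR (0.18 ± 0.20) was not called, and MDM2 (-0.33 ± 0.23) only with the block (adjusted p = 0.0262). Of 5977 genes 1095 changed, 447 up and 648 down, 114 by 2-fold or more. Without vehicle array 3 903 changed, and 2497 with the block.
Both drugs together in SKBR3 gave the division response of rapamycin and the inflammatory response of doxorubicin. CXCL8 (at least 3.48), CFB (2.59 ± 0.30), TNFAIP3 (2.16 ± 0.28), IGFL1 (1.92 ± 0.21) and the peptide transporter TAP1 (1.84 ± 0.18) were among the most raised. DLGAP5 (-2.05 ± 0.31), CEP55 (-1.71 ± 0.32), SHCBP1 (-1.66 ± 0.26), cyclin CCNA2 (-1.63 ± 0.20) and the cytokinesis gene ANLN (-1.61 ± 0.26) fell most, and TOP2A fell by 1.36 ± 0.29. G2 and mitosis held as called down (0 of 24 rose and 23 fell, 0 and 24 adjusted over the list alone, median -1.25, camera adjusted p = 4.13e-19). The NF-kB targets held as called up (3 of 3 rose and 0 fell, 3 and 0 adjusted over the list alone, median 2.16, camera adjusted p = 4.87e-06). CXCL8 and TNFAIP3 entered that list only through arrays with doxorubicin. DNA replication was called down (1 of 28 rose and 15 fell, 1 and 17 adjusted over the list alone, median -0.44, camera adjusted p = 3.47e-06, adjusted p = 0.11 with an estimated correlation). So was cholesterol synthesis (0 of 13 rose and 8 fell, 0 and 8 adjusted over the list alone, median -0.40, camera adjusted p = 0.00562, adjusted p = 0.147 with an estimated correlation). The FOXO targets were called up (3 of 7 rose and 0 fell, 3 and 0 adjusted over the list alone, median 0.45, camera adjusted p = 0.00074, adjusted p = 0.0589 with an estimated correlation). Of the ERBB2 neighbours 2 of 10 rose and 2 fell, 3 and 3 adjusted over the list alone, and each of the 4 lost its call without some array. Of the hypoxia targets 3 of 11 rose and 1 fell, 3 and 2 adjusted over the list alone, median -0.19, camera adjusted p = 0.693. Median and mean were negative against a camera direction of up. In all 1313 of 5977 genes changed, 499 up and 814 down, 112 by 2-fold or more. The count was 866 without vehicle array 1, 851 without vehicle array 4 and 873 without combined array 2, 976 without vehicle array 3, and 3020 with the block.

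**Figure D3:**
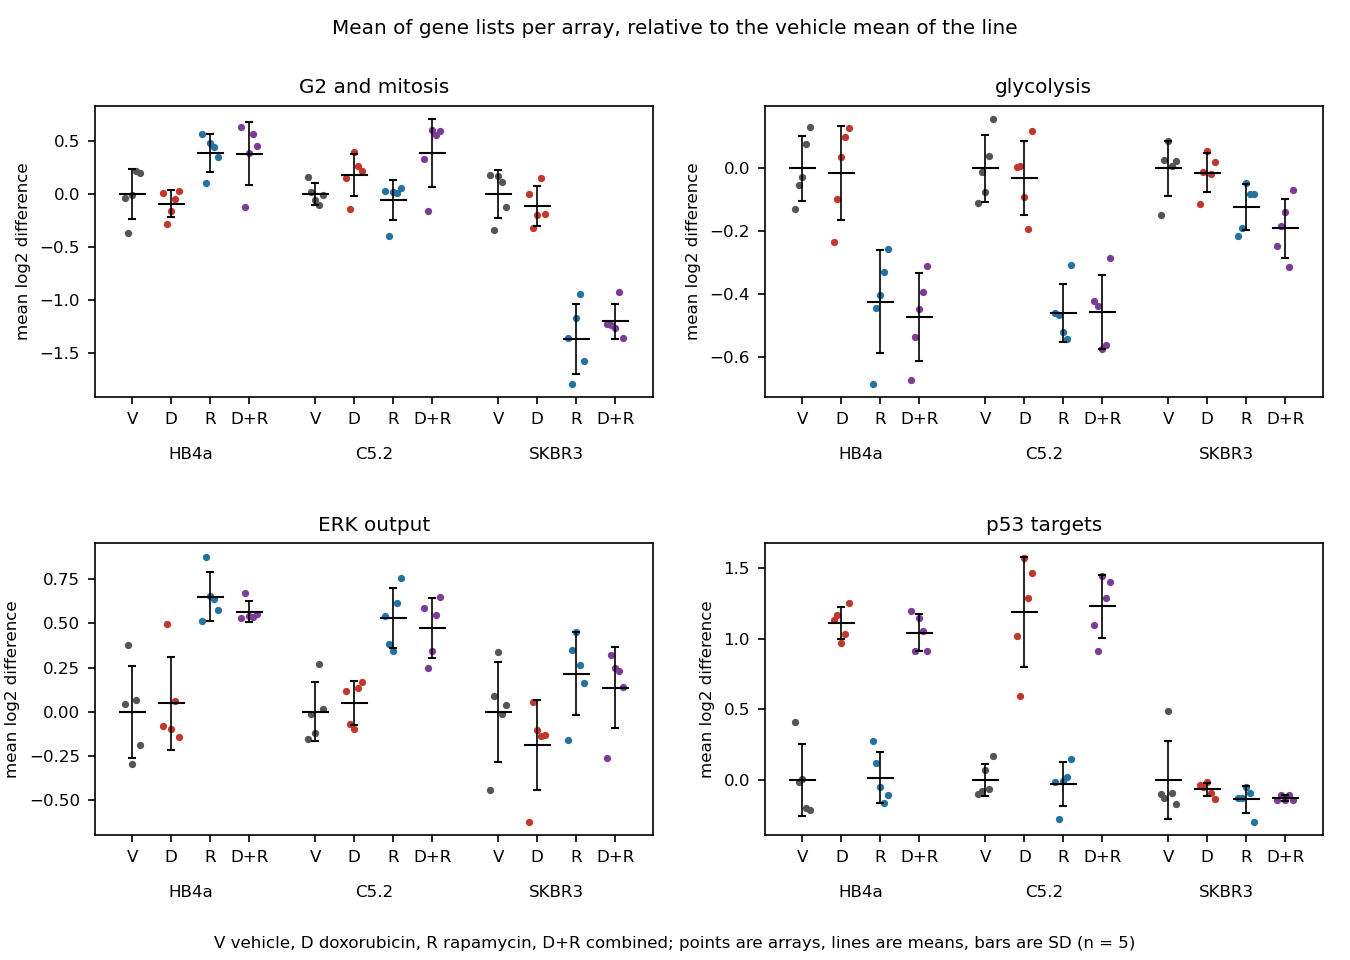
Mean log2 value of a gene list on each array, relative to the line's vehicle mean (vertical axes), by line and treatment (horizontal axes), with points for arrays, lines for means and bars for SD (n = 5). The p53 targets moved up with doxorubicin in HB4a and C5.2 (median changes 0.97 and 1.01) and not in SKBR3 (-0.03), and the G2 and mitosis genes fell as a list with rapamycin in SKBR3 (median -1.40).

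Both drugs together were next set against doxorubicin alone. In HB4a, DDIT4 (-1.55 ± 0.21), the water channel AQP3 (-1.48 ± 0.32) and KRT15 (-1.25 ± 0.25) fell most, while CCN2 (2.02 ± 0.25), EGR1 (1.62 ± 0.30) and PTGS2 (1.43 ± 0.32) rose. Glycolysis was called down (0 of 19 rose and 9 fell, 0 and 15 adjusted over the list alone, median -0.38, camera adjusted p = 1.84e-16). Cholesterol synthesis was called down too (0 of 13 rose and 0 fell, 0 and 0 adjusted over the list alone, median -0.31, camera adjusted p = 0.000338). The FOXO targets were called up (4 of 12 rose and 0 fell, 6 and 0 adjusted over the list alone, median 0.36, camera adjusted p = 1.35e-07). So was ERK output (3 of 14 rose and 0 fell, 7 and 0 adjusted over the list alone, median 0.34, camera adjusted p = 1.89e-08). G2 and mitosis was called up (2 of 24 rose and 0 fell, 9 and 0 adjusted over the list alone, median 0.31, camera adjusted p = 1.34e-10). These 5 calls held. In C5.2, KRT13 (-1.90 ± 0.38), KRT19 (-1.29 ± 0.28) and KRT5 (-1.27 ± 0.28) fell and EGR1 (2.42 ± 0.34), MAFF (1.17 ± 0.10) and CCN2 (1.13 ± 0.25) rose. There the ATF4 targets were called down (0 of 22 rose and 11 fell, 0 and 14 adjusted over the list alone, median -0.37, camera adjusted p = 1.45e-07, adjusted p = 0.0801 with an estimated correlation). Glycolysis was called down there (0 of 17 rose and 10 fell, 0 and 15 adjusted over the list alone, median -0.36, camera adjusted p = 1.06e-06, adjusted p = 0.184 with an estimated correlation), and neither C5.2 call held. In SKBR3, MCM10 (-1.90 ± 0.26), PBK (-1.85 ± 0.30) and the proliferation marker MKI67 (-1.67 ± 0.33) fell, CCNO (1.95 ± 0.17), RIPOR3 (1.50 ± 0.25) and EMP1 (1.44 ± 0.12) rose. DNA replication held its call (0 of 28 rose and 24 fell, 0 and 24 adjusted over the list alone, median -0.62, camera adjusted p = 9.83e-14). The G2 and mitosis list did not hold (0 of 24 rose and 24 fell, 0 and 24 adjusted over the list alone, median -1.09, camera adjusted p = 1.08e-16, adjusted p = 0.051 with an estimated correlation). In HB4a 159 genes changed (71 up and 88 down, by 2-fold 13 and 9), with 44.7% of calls up, or 33.3% once each array was centred on its own median. In C5.2 852 changed (109 up and 743 down, by 2-fold 9 and 9), and in SKBR3 1317 (443 up and 874 down). The HB4a count was 99 without doxorubicin array 4 and 96 without combined array 4. The C5.2 count was 560 without doxorubicin array 1, 472 without doxorubicin array 6, 468 without combined array 3 and 481 without combined array 4. With the experiment number as a block it was 2394 in C5.2 and 2962 in SKBR3.
Adding doxorubicin to rapamycin brought p53 targets up in HB4a and C5.2 and NF-kB targets up in SKBR3. GDF15 rose by 2.71 ± 0.25 in HB4a and 3.12 ± 0.24 in C5.2 against rapamycin alone, CDKN1A by 1.91 ± 0.16 and 2.20 ± 0.20, and AKR1B10 by 2.35 ± 0.29 in HB4a. FOXQ1 (-1.85 ± 0.26), the interleukin receptor IL1RL1 (-1.62 ± 0.30) and RGCC (-1.52 ± 0.22) fell most in HB4a, and KRT13 (-1.99 ± 0.38), SCNN1G (-1.39 ± 0.31) and the pseudokinase TRIB1 (-1.06 ± 0.17) in C5.2. The p53 list held in HB4a (15 of 22 rose and 0 fell, 19 and 0 adjusted over the list alone, median 0.94, camera adjusted p = 4.06e-22). It held in C5.2 as well (17 of 20 rose and 0 fell, 18 and 0 adjusted over the list alone, median 1.15, camera adjusted p = 5.54e-32). Ribosome biogenesis held as called down in HB4a (0 of 23 rose and 4 fell, 0 and 17 adjusted over the list alone, median -0.42, camera adjusted p = 3.62e-10). IRS1 fell by 1.34 ± 0.16 in HB4a, and KIF2C rose by 0.75 ± 0.09 in C5.2. In HB4a the FOXO targets were called down (0 of 12 rose and 4 fell, 0 and 5 adjusted over the list alone, median -0.37, camera adjusted p = 0.000161, adjusted p = 0.112 with an estimated correlation). In C5.2 the mitotic genes were called up (12 of 25 rose and 0 fell, 13 and 0 adjusted over the list alone, median 0.48, camera adjusted p = 7.56e-14, adjusted p = 0.11 with an estimated correlation). In SKBR3, CXCL8 rose by at least 3.47, TNFAIP3 by 2.50 ± 0.28 and CFB by 2.06 ± 0.30, and no gene fell. The helicase subunit MCM7 rose by 0.51 ± 0.09. NF-kB targets held as called up (3 of 3 rose and 0 fell, 3 and 0 adjusted over the list alone, median 2.50, camera adjusted p = 4.23e-17). DNA replication held as called up (2 of 28 rose and 0 fell, 14 and 0 adjusted over the list alone, median 0.27, camera adjusted p = 3.92e-17). So did the ATF4 targets (0 of 21 rose and 0 fell, 0 and 0 adjusted over the list alone, median 0.17, camera adjusted p = 0.000225). The counts were 545 in HB4a (349 up and 196 down), 402 in C5.2 (303 up and 99 down) and 33 in SKBR3. The HB4a count was 330 without combined array 6, and the SKBR3 count 56 without combined array 4. With the experiment number as a block it was 1394 in C5.2 and 397 in SKBR3.
No gene departed from the sum of the single-drug effects in any line at an adjusted p under 0.05, of 6167, 6292 and 5977 tested. CDKN1A departed by 0.16 ± 0.23 in HB4a and 0.05 ± 0.28 in C5.2, ERBB2 by 0.03 ± 0.21 in SKBR3 and TOP2A by -0.15 ± 0.62, 0.36 ± 0.40 and 0.02 ± 0.42 in the 3 lines. Before adjustment 19, 77 and 61 genes had p under 0.05, fewer than the 1 in 20 that chance alone gives. The fit without pairing counts differences shared by arrays of one experiment as error. This test was strict. With the block no gene departed in SKBR3, where pairing held, or C5.2, and 1 in HB4a. Low counts do not show additivity. On simulated HB4a arrays without such shared differences 47 of 67 genes departing by 1 log2 unit were recovered and 10 of 67 by 0.5. Departures under about 1 were often missed. Mitotic genes were called above additivity in HB4a (camera adjusted p = 8.28e-07, adjusted p = 0.315 with an estimated correlation), C5.2 (camera adjusted p = 3.53e-17, adjusted p = 0.1 with an estimated correlation) and SKBR3 (camera adjusted p = 5.48e-15, adjusted p = 0.0716 with an estimated correlation). The histone genes were called so in SKBR3 (camera adjusted p = 1.75e-07, adjusted p = 0.0503 with an estimated correlation), and no such call held. The fry test asks whether a list's genes move on balance one way, without regard to other genes. Fry gave adjusted p = 0.958, 0.952 and 0.647 for the G2 and mitosis genes.
The single-drug responses kept their shape when the other drug was present. Across genes, the doxorubicin changes without and with rapamycin correlated at r = 0.913 in HB4a (± 0.0835, jackknife over arrays), 0.842 in C5.2 and 0.676 in SKBR3 (± 0.232). GDF15 and CDKN1A in HB4a and C5.2, and CXCL8 in SKBR3, were among the genes raised both ways. HB4a and C5.2 shared their doxorubicin response at r = 0.779 ± 0.112 and their rapamycin response at 0.782 ± 0.207. HB4a and SKBR3 reached 0.2 ± 0.281 and 0.174 ± 0.235, within their jackknife error of 0. Over the genes called in HB4a these were 0.102 and 0.555, and for rapamycin 81.4% of those genes had the same sign in SKBR3. Without HB4a rapamycin array 1 the first correlation above was 0.822. Genes are not independent replicates, and estimates that share a group's arrays share its error.
C5.2 answered each drug much as HB4a did. The mitochondrial gene MGARP rose less in C5.2 with doxorubicin (difference -2.14 ± 0.27) and with both drugs (-2.09 ± 0.27). KRT13 fell further in C5.2 with both drugs (-2.07 ± 0.42), and the retinal reductase DHRS3 stood higher (0.86 ± 0.18). CDKN1A (0.40 ± 0.27), MDM2 (0.25 ± 0.54) and ERBB2 (-0.19 ± 0.20) had no called difference in their doxorubicin response. IRS2 had one only with the experiment number as a block, with doxorubicin (0.62 ± 0.34, adjusted p = 0.0148) and with both drugs (0.50 ± 0.34, 0.024), where pairing did not hold. The NF-kB targets were called lower in response to both drugs (0 of 5 higher and 1 lower, 0 and 5 adjusted over the list alone, median -1.03, camera adjusted p = 3.43e-07), a call that held. No difference was called for a single mitotic gene. Their list was called higher with doxorubicin (0 of 27 higher and 0 lower, 3 and 0 adjusted over the list alone, median 0.31, camera adjusted p = 2.06e-13, adjusted p = 0.104 with an estimated correlation). It was called lower with rapamycin (0 of 27 higher and 0 lower, 0 and 8 adjusted over the list alone, median -0.38, camera adjusted p = 2.80e-09, adjusted p = 0.245 with an estimated correlation), and neither call held. For the lysosome and rapamycin, median -0.06 and mean 0.02 differed in sign with camera direction up. The median difference over all genes was -0.108 for rapamycin and -0.116 for both drugs, so values here stand against those. With doxorubicin 7 genes differed, all lower in C5.2. That count was 4 without HB4a vehicle arrays 1, 2, 3 and 4 and C5.2 doxorubicin array 6 in turn and 3 without HB4a vehicle array 6, HB4a doxorubicin arrays 4 and 6, C5.2 vehicle arrays 3, 4 and 6 and C5.2 doxorubicin arrays 1 and 4 in turn, and 137 with the experiment number as a block. With rapamycin 0 of 6962 differed, 356 before adjustment, 176 with that block, 502 with array weights and 3 without HB4a rapamycin array 1. With both drugs 26 differed, 3 higher and 23 lower, and the count was 54 without HB4a combined array 1, 16 without HB4a combined array 4, 15 without HB4a combined array 6, 14 without C5.2 vehicle array 3 and 17 without C5.2 combined array 4.
SKBR3 answered both drugs in part differently from HB4a. With doxorubicin, GDF15 (-3.47 ± 0.59), TP53I3 (-2.56 ± 0.45), the autophagy gene ELAPOR1 (-2.34 ± 0.30) and CDKN1A (-1.70 ± 0.39) responded less in SKBR3, and CXCL8 (adjusted p = 1.14e-06, levels partly at background), the protease inhibitor SERPINA3 (2.66 ± 0.45) and CFB (2.07 ± 0.39) more. SKBR3 vehicle array 3 inflated the p53 targets here: without it GDF15 differed by -2.74, TP53I3 by -2.02 and CDKN1A by -1.26. With rapamycin, DLGAP5 (-2.94 ± 0.49), HMMR (-2.84 ± 0.48), NUF2 (-2.74 ± 0.52) and TOP2A (-2.55 ± 0.56) fell further, and CCNO (2.11 ± 0.23) and AQP3 (1.60 ± 0.36) stood higher. With both drugs, GDF15 (-2.87 ± 0.59, or -2.15 without that array), ASPM (-2.76 ± 0.56) and DEPDC1 (-2.66 ± 0.46) stood lower and SERPINA3 (3.22 ± 0.45) and CXCL8 (adjusted p = 2.11e-05) higher. With doxorubicin the p53 targets held as lower (0 of 22 higher and 12 lower, 0 and 20 adjusted over the list alone, median -1.02, camera adjusted p = 6.66e-24). DNA replication held as higher (5 of 30 higher and 0 lower, 9 and 0 adjusted over the list alone, median 0.22, camera adjusted p = 3.40e-08). With rapamycin the G2 and mitosis genes held as lower (28 of 28 lower, also adjusted over the list alone, median -1.59, camera adjusted p = 6.88e-49). DNA replication did so too (0 of 30 higher and 13 lower, 0 and 18 adjusted over the list alone, median -0.60, camera adjusted p = 3.37e-15). With both drugs the p53 targets held as lower (0 of 22 higher and 18 lower, 0 and 21 adjusted over the list alone, median -0.96, camera adjusted p = 1.47e-14). So did G2 and mitosis (0 of 28 higher and 27 lower, 0 and 28 adjusted over the list alone, median -1.40, camera adjusted p = 4.75e-30). Histone genes held as higher (5 of 5 higher and 0 lower, 5 and 0 adjusted over the list alone, median 0.98, camera adjusted p = 1.99e-08). The NF-kB targets were called higher with doxorubicin (3 of 6 higher and 0 lower, 3 and 0 adjusted over the list alone, median 0.61, camera adjusted p = 3.12e-05, adjusted p = 0.0709 with an estimated correlation). They were called lower with rapamycin (0 of 6 higher and 2 lower, 0 and 5 adjusted over the list alone, median -0.84, camera adjusted p = 0.00108, adjusted p = 0.224 with an estimated correlation). Of 7270 gene responses 281 differed with doxorubicin (80 higher and 201 lower), 366 with rapamycin (114 and 252) and 714 with both (246 and 468), the last against a median of -0.101 over all genes. With the block the first 2 counts were 1157 and 1634, and 222 and 317 without SKBR3 vehicle array 3.
Some lists showed little. The pentose phosphate genes had no camera call in the 9 treatments against vehicle, with medians from -0.09 to 0.27. No leukocyte or endothelial marker passed the filter. Against vehicle without a block, hypoxia targets were called only in HB4a with both drugs, down (0 of 10 rose and 2 fell, 0 and 3 adjusted over the list alone, median -0.30, camera adjusted p = 0.0397, adjusted p = 0.253 with an estimated correlation), a call lost without vehicle arrays 1, 3 and 6 and combined arrays 3 and 6. They were called higher in the C5.2 responses than in HB4a with doxorubicin (camera adjusted p = 0.0108, adjusted p = 0.392 with an estimated correlation), a call lost without HB4a vehicle array 3 and HB4a doxorubicin array 2, rapamycin (camera adjusted p = 0.000517, adjusted p = 0.256 with an estimated correlation) and both (camera adjusted p = 7.62e-05, adjusted p = 0.236 with an estimated correlation). Basal markers were called up with rapamycin in C5.2 (1 of 11 rose and 1 fell, 3 and 1 adjusted over the list alone, median 0.24, camera adjusted p = 0.0153, adjusted p = 0.522 with an estimated correlation). They were called up with it in HB4a too (1 of 12 rose and 1 fell, 4 and 1 adjusted over the list alone, median 0.34, camera adjusted p = 0.0496, adjusted p = 0.182 with an estimated correlation), a call lost without vehicle arrays 1, 4 and 6 and rapamycin arrays 1, 2, 3 and 6 in turn. Mesenchymal markers were called down with doxorubicin in HB4a (0 of 8 rose and 2 fell, 1 and 4 adjusted over the list alone, median -0.32, camera adjusted p = 0.0289, adjusted p = 0.167 with an estimated correlation). The 17q12 genes had no call in any treatment against vehicle without a block. With it they were called up with doxorubicin in HB4a (camera adjusted p = 0.0277), and the hypoxia targets were called down (0.0428). Over all results 206 of 538 list tests gave a camera call and 42 of these held with an estimated correlation, all of them named above as held. In this section the p is given with an estimated correlation wherever a described call was lost with it. Other calls are not described, and none of them held.
Others of the genes always named were called only with the block where pairing held. Against vehicle these were CDKN1A with rapamycin in C5.2 (-0.33 ± 0.20, adjusted p = 0.0325 with the block) and, in SKBR3 with both drugs, MDM2 (-0.52 ± 0.23, 0.00101) and EGFR (0.23 ± 0.20, 0.0452). For both drugs against doxorubicin they were MDM2 (0.51 ± 0.39, 0.031), TOP2A (0.79 ± 0.28, 0.00451) and IRS2 (0.82 ± 0.31, 1.43e-05) in C5.2, and ERBB2 (0.24 ± 0.15, 0.0107, doxorubicin array 1 low at 10.85) and MDM2 (-0.35 ± 0.23, 0.0153) in SKBR3. Among differences from HB4a in the doxorubicin response they were MDM2 (-1.43 ± 0.43, 1.40e-05), ERBB2 (-0.34 ± 0.24, 0.0468) and EGFR (0.43 ± 0.23, 0.0265) in SKBR3. Rapamycin added EGFR (-0.37 ± 0.23, 0.0496) and IRS2 (0.0129, partly at background) there.

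**Figure D4:**
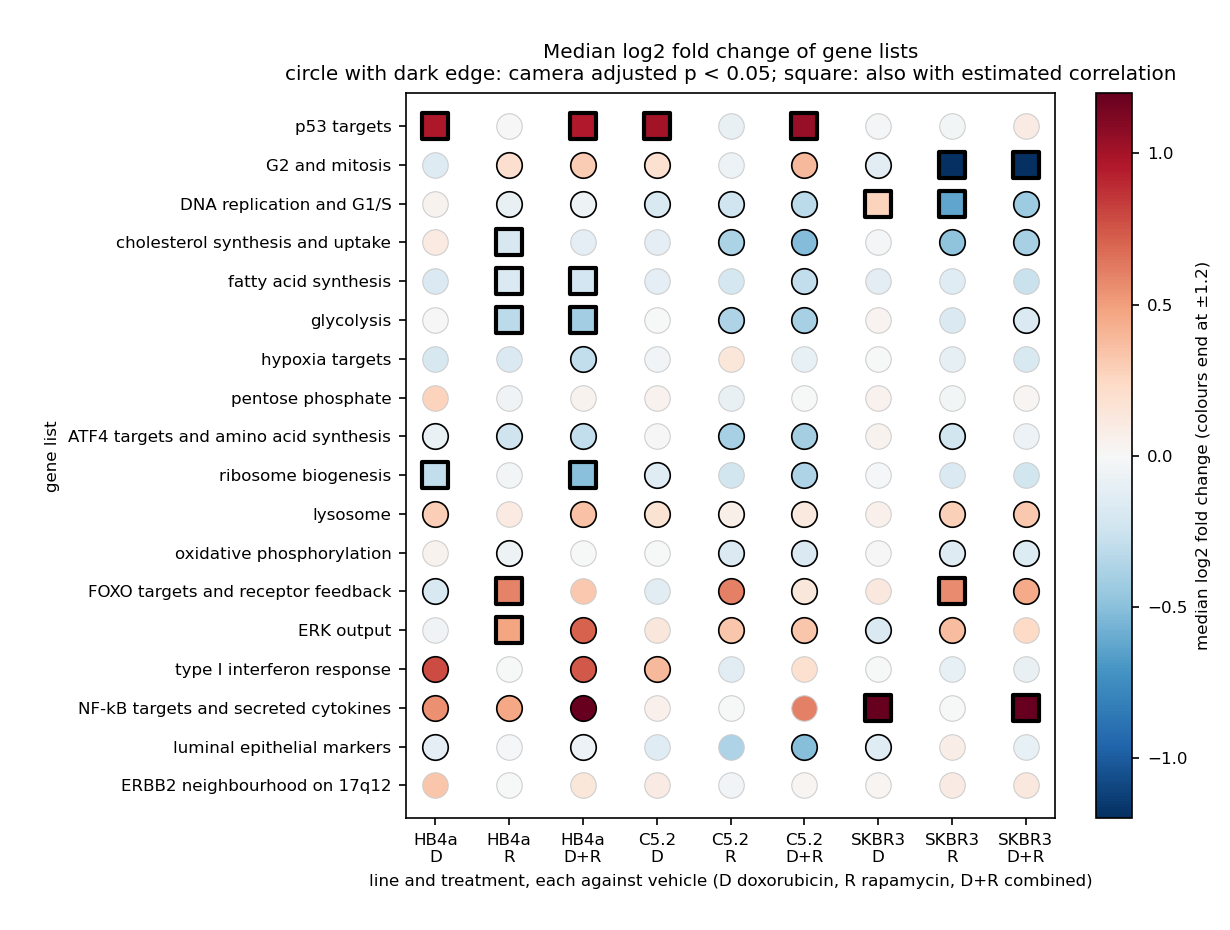
Median log2 change of 18 of the 23 gene lists (vertical axis, colour scale in log2 units) for the 9 treatments against vehicle (horizontal axis), with dark circles where camera called the list and squares where the call held with an estimated correlation. The extremes were the NF-kB targets in SKBR3 with both drugs (2.16) and the G2 and mitosis genes in SKBR3 with rapamycin (-1.40).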

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

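The tests of the p53 pattern, the CXCL8 test of SKBR3 vehicle array 3 and the search for its extra RNA's source were chosen after the results were seen, the others before.
CDKN1A, GDF15 and TP53I3, targets of the damage sensor p53, moved differently with doxorubicin in SKBR3 and HB4a. The p53 list's median difference in response was -1.02 with doxorubicin and -0.96 with both drugs. The G2 and mitosis list differed by -1.59 with rapamycin and -1.40 with both, and DNA replication by 0.215 with doxorubicin and -0.598 with rapamycin. Histone genes differed by 0.975 with both drugs, and the NF-kB targets by -1.03 between C5.2 and HB4a with both. These 8 list differences passed camera with both correlations. Genes passing a test of the difference numbered 281, 366 and 714 between SKBR3 and HB4a with doxorubicin, rapamycin and both. Between C5.2 and HB4a they numbered 7 with doxorubicin and 26 with both.
Why the p53 targets moved up in HB4a and C5.2 and not in SKBR3 was weighed. Levels near the floor are argued against: the 11 targets above the filter in both lines had a median change of -0.0281 in SKBR3 against 0.901 in HB4a. Cells that missed the drug stay possible. CXCL8 lay above all arrays without doxorubicin on 10 of 10 with it, but was named for such separation. A difference in p53 function between the lines stays a candidate explanation that was not tested.
The fall of the G2 and mitosis genes with rapamycin in SKBR3 was weighed next. A shift of whole arrays is argued against by a list median of -1.38 after quantile normalization, the nearer to 0 of the 2 scalings tried, against -1.4 before, and by a median of -0.0316 over all tested genes. RNA quality stays open, because its test moved almost nothing: the list median was -1.39 with the actin and GAPDH end differences as covariates, which moved a gene by a median of 0.0147 against a median standard error of 0.137. Slower division of SKBR3 under rapamycin is another candidate, with cell numbers not analysed here.
SKBR3 vehicle array 3 was weighed last. GPX1, NNMT, LGALS3, TPM2, MXRA7, DKK1, SPARC, BEX3 and MSN, high in HB4a and C5.2 and near the floor in SKBR3, stood a median 3.53 above the other 4 vehicle arrays there, while no other SKBR3 array passed 0.256 against its own group. That argues against a damage response of the culture alone. An exchange with doxorubicin array 3 is argued against by CXCL8 at 1.13 on this array and 5.05 on that one. RNA of HB4a stays a candidate source: in a fit over 198 genes all 10 HB4a arrays with doxorubicin matched better than every other array tried, at a share of 2.2 to 2.55%. Without that array the SKBR3 doxorubicin calls of the G2 list (adjusted p = 0.0638) and ERK output (0.0638) ended, neither of which held with an estimated correlation, as did those of EMP1 and SNHG19.
Single arrays stood far from their group in 27 of 168 groups of 5, and chance flags about 1 in 20 groups. ERBB2 was low on C5.2 vehicle array 1 (11.63), SKBR3 vehicle array 1 (10.87) and SKBR3 doxorubicin array 1 (10.85). EGFR was low on SKBR3 arrays 1 of vehicle (5.08), doxorubicin (5.07) and combined (5.27), and on C5.2 rapamycin array 2 (6.06). TOP2A was low on C5.2 rapamycin array 2 (5.88) and SKBR3 vehicle array 2 (7.59). IRS2 was low on HB4a rapamycin array 2 (8.56) and C5.2 doxorubicin array 2 (6.87) and high on SKBR3 vehicle array 3 (3.30). On that array CDKN1A (6.59) and the p53 list mean (5.13) were high. MDM2 was high on HB4a rapamycin array 1 (7.02), and the G2 list mean low on C5.2 rapamycin array 2 (6.31). Mean correlation with the group was low on HB4a doxorubicin array 1 (0.988) and rapamycin array 1 (0.973), SKBR3 doxorubicin array 1 (0.989) and the C5.2 arrays 2 of doxorubicin (0.986), rapamycin (0.985) and combined (0.979). The quartile range was narrow on C5.2 doxorubicin array 2 (3.09) and rapamycin array 2 (3.02). The GAPDH end difference was high on HB4a vehicle array 4 (0.36), HB4a rapamycin array 4 (1.67) and C5.2 vehicle array 2 (0.76).
Other splits of the same arrays into groups of equal size were counted, 100 per result with the real one, for the genes led by GDF15, CXCL8 and DLGAP5 and all others. The real count was the highest, which unadjusted does not exclude chance, for (real and highest other) HB4a doxorubicin 705 and 1, rapamycin 196 and 1, combined 1074 and 4, combined against doxorubicin 159 and 0, C5.2 doxorubicin 205 and 24, rapamycin 1097 and 0, combined 1320 and 374, SKBR3 rapamycin 1095 and 353, combined against doxorubicin 1317 and 735, C5.2 and SKBR3 against HB4a in vehicle 3425 and 1931, and 5618 and 4400. SKBR3 against HB4a differences gave 281 and 255 (doxorubicin), 366 and 357 (rapamycin) and 714 and 626 (combined). Splits also break each line's response, so these show nothing on chance. Chance stays open, with unadjusted shares under 0.05 and 2 or 3 of 100 splits reaching the real count, itself included, for HB4a combined against rapamycin 545 and 968, C5.2 combined against doxorubicin 852 and 1296, combined against rapamycin 402 and 503, SKBR3 doxorubicin 50 and 375, combined 1313 and 1865, combined against rapamycin 33 and 854, C5.2 against HB4a doxorubicin difference 7 and 348 and combined difference 26 and 912. Where pairing held within a line, the real split led the 16 that part all 5 pairs, too few to exclude chance. In SKBR3 with both drugs the larger split exchanged vehicle array 2 with combined array 4. Counts several times the real one, such as 375 against 50 for SKBR3 doxorubicin, point to a structure of the samples: that split put the arrays numbered 1 and 4 of both groups on the same side. Where no gene was called every split reaches that, so nothing on chance follows, and the highest others were 1463 (HB4a), 1041 (C5.2) and 1303 (SKBR3) for non-additive effects and 285 (C5.2 against HB4a rapamycin difference).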

How the results depend on the processing

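The filters at log2 3, the fits without arrays that stood apart, the random block, the block with only the arrays compared and the lists without SKBR3 vehicle array 3 were chosen after the data were seen, and the other settings before. GDF15, CXCL8 and DLGAP5 kept their direction and side of the threshold in every setting run, while CDKN1A changed sign in some contrasts where it was not called. Of the single-gene results over all settings 16169 kept their side of the threshold, 994 fell short of it, 93 passed it and 4 reversed. Of the list results 9612 kept their side, 480 fell short, 288 passed and none reversed. Of the counts 491 stayed within 1.5 times the reported one and 167 did not, and of the 2-fold counts 540 and 118. The reversals came with the mean of all probe sets: KRT19 in SKBR3 with both drugs (0.0137), CCNB1 in C5.2 against HB4a (0.0486), HK2 in SKBR3 against HB4a (-1.50) and AGR2 in the SKBR3 difference with both drugs (-0.0835). The cause was not tested. Signal over background limits genes near the floor, where the filter decides how many are tested, and 5 arrays per group limit the rest.
Counts for GDF15, CXCL8, DLGAP5 and the other called genes moved beyond 1.5 times the reported value as follows, with the cause not tested except that filters change how many genes are tested. With the experiment number as a block the counts were HB4a doxorubicin 2014, rapamycin 1008, combined 2307, combined against doxorubicin 973, combined against rapamycin 1754, non-additive effect 1, C5.2 doxorubicin 1093, rapamycin 2781, combined 2722, combined against doxorubicin 2394, combined against rapamycin 1394, SKBR3 doxorubicin 299, rapamycin 2497, combined 3020, combined against doxorubicin 2962, combined against rapamycin 397, C5.2 against HB4a doxorubicin difference 137, rapamycin difference 176, combined difference 696, SKBR3 against HB4a doxorubicin difference 1157, rapamycin difference 1634, combined difference 2317. With that block and only the arrays compared they were HB4a doxorubicin 2264, rapamycin 1142, combined against doxorubicin 583, combined against rapamycin 921, C5.2 doxorubicin 741, rapamycin 2316, combined against doxorubicin 2319, combined against rapamycin 2073, SKBR3 doxorubicin 842, rapamycin 2315, combined 2144, combined against doxorubicin 2196, combined against rapamycin 585. Array weights gave HB4a doxorubicin 1873, rapamycin 607, combined 2152, combined against doxorubicin 647, combined against rapamycin 1178, C5.2 doxorubicin 717, rapamycin 3064, combined 3013, combined against doxorubicin 2698, combined against rapamycin 1018, SKBR3 doxorubicin 200, combined 2681, combined against doxorubicin 2230, combined against rapamycin 116, non-additive effect 2, C5.2 against HB4a doxorubicin difference 44, rapamycin difference 502, combined difference 1101, SKBR3 against HB4a doxorubicin difference 763, rapamycin difference 580, combined difference 1475. A fit of all 60 arrays gave HB4a doxorubicin 1112, rapamycin 328, combined against doxorubicin 297, combined against rapamycin 886, SKBR3 doxorubicin 89, combined against rapamycin 59. A fit of only the arrays compared gave HB4a rapamycin 105, combined against rapamycin 199, C5.2 doxorubicin 70, combined against doxorubicin 392, SKBR3 doxorubicin 27, combined 853, combined against rapamycin 9. The filter at log2 7 gave HB4a doxorubicin 311, rapamycin 124, combined 494, combined against rapamycin 263, C5.2 doxorubicin 101, rapamycin 565, combined 645, combined against doxorubicin 417, combined against rapamycin 192, SKBR3 doxorubicin 16, rapamycin 610, combined 668, combined against doxorubicin 657, combined against rapamycin 13, C5.2 against HB4a in vehicle 1392, doxorubicin difference 0, SKBR3 against HB4a in vehicle 2356, doxorubicin difference 107, rapamycin difference 211, combined difference 335. The filter at log2 3 gave C5.2 doxorubicin 333, SKBR3 doxorubicin 89, combined against rapamycin 54, C5.2 against HB4a in vehicle 5537, doxorubicin difference 12, rapamycin difference 2, combined difference 44. No filter gave SKBR3 doxorubicin 88, combined against rapamycin 52, C5.2 against HB4a in vehicle 7966, doxorubicin difference 17, rapamycin difference 2, SKBR3 against HB4a in vehicle 12276. The mean of all probe sets gave HB4a doxorubicin 454, combined 700, combined against rapamycin 363, SKBR3 combined 841, C5.2 against HB4a in vehicle 2079, rapamycin difference 2, SKBR3 against HB4a in vehicle 3326. Array centring gave C5.2 against HB4a doxorubicin difference 3, combined difference 17. Quantile normalization gave C5.2 combined against doxorubicin 502, C5.2 against HB4a doxorubicin difference 4. Without the arrays that stood apart they were HB4a doxorubicin 1494, combined 1621, combined against doxorubicin 246, C5.2 doxorubicin 561, combined against rapamycin 625, C5.2 against HB4a doxorubicin difference 11, rapamycin difference 1, combined difference 95, SKBR3 against HB4a doxorubicin difference 536. The random block kept both vehicle counts within that bound. Leaving out each array in turn moved these counts: HB4a doxorubicin 428 to 953, combined against doxorubicin 96 to 167, combined against rapamycin 330 to 788, C5.2 doxorubicin 97 to 252, rapamycin 644 to 1287, combined against doxorubicin 468 to 1072, SKBR3 doxorubicin 31 to 50, combined 851 to 1873, combined against rapamycin 25 to 56, C5.2 against HB4a doxorubicin difference 3 to 9, rapamycin difference 0 to 3, combined difference 14 to 54. The response correlation of doxorubicin without and with rapamycin in HB4a ran from 0.822, without rapamycin array 1, to 0.91. Over called genes only, response correlations were 0.961 for doxorubicin without and with rapamycin in C5.2 and 0.932 in SKBR3, 0.555 for rapamycin between HB4a and SKBR3 and 0.594 between C5.2 and SKBR3. The block with only the arrays compared was used for comparisons of 2 groups of a line.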

Other observations

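The gene families and crossed pairs here were chosen after the values were seen, and none of the directions described here changed with array centring or quantile normalization.
The peptide transporter TAP1 rose with doxorubicin in SKBR3 by 1.78 ± 0.18, and the HLA class I and peptide loading genes lay above the other genes with a median of 0.51 (2 of 8 rose, camera adjusted p = 3.63e-12, adjusted p = 0.000839 with an estimated correlation). With both drugs TAP1 rose by 1.84 ± 0.18 and HLA-B by 0.57 ± 0.18, and 6 of 8 members rose (camera adjusted p = 2.37e-06, adjusted p = 0.0172 with an estimated correlation). In HB4a with doxorubicin TAP1 rose by 0.75 ± 0.17, the proteasome subunit PSMB9 by 0.76 ± 0.23 and HLA-B by 0.41 ± 0.11, but the family's call did not hold (camera adjusted p = 0.00307, adjusted p = 0.29 with an estimated correlation).
MT2A and MT1X, metallothioneins that bind zinc and copper, fell with doxorubicin and rose with rapamycin in SKBR3. MT2A changed by -0.61 ± 0.11 and MT1X by -0.54 ± 0.12 with doxorubicin (camera adjusted p = 3.63e-12, adjusted p = 0.0223 with an estimated correlation), and by 0.77 ± 0.11 and 0.88 ± 0.12 with rapamycin, where all 6 members rose without the call holding (camera adjusted p = 7.54e-08, adjusted p = 0.173 with an estimated correlation). In HB4a all 6 tested fell with doxorubicin (median -0.28, camera adjusted p = 3.36e-11, adjusted p = 0.0261 with an estimated correlation). In vehicle all 6 were lower in C5.2 than in HB4a (median -1.58, camera adjusted p = 6.17e-11, adjusted p = 0.0321 with an estimated correlation).
Keratins were called down with both drugs in HB4a, with KRT13 at -1.46 ± 0.16, KRT15 at -1.45 ± 0.25 and KRT8 at -0.50 ± 0.13 (6 of 9 fell, camera adjusted p = 1.35e-07, adjusted p = 0.016 with an estimated correlation). In C5.2 6 of 8 fell, and the call did not hold (camera adjusted p = 1.47e-05, adjusted p = 0.115 with an estimated correlation). With rapamycin alone 4 fell in HB4a and 4 in C5.2, without holding. The tRNA synthetases, which charge tRNA with amino acids, were called down in HB4a with rapamycin (0 of 14 tested fell, camera adjusted p = 0.00492, adjusted p = 0.0448 with an estimated correlation) and with both drugs (4 fell, camera adjusted p = 5.63e-05, adjusted p = 0.00297 with an estimated correlation). In C5.2 10 fell with rapamycin (camera adjusted p = 0.000369, adjusted p = 0.183 with an estimated correlation) and 9 with both, with CARS1 at -0.59 ± 0.08 and AARS1 at -0.36 ± 0.08, without holding (camera adjusted p = 2.27e-05, adjusted p = 0.115 with an estimated correlation). In SKBR3 the 3 MAGE-A genes tested stood far above HB4a (median at least 6.77, camera adjusted p = 0.000104, adjusted p = 0.0149 with an estimated correlation). In all 12 families were tested.
The arrays numbered 2 and 3 of HB4a with both drugs did not pair with the vehicle or rapamycin arrays of equal number. Their residual correlations with vehicle were -0.211 and -0.536, and the other 3 numbers lay above 0.1. Crossed, combined array 3 correlated with the arrays 2 of vehicle, doxorubicin and rapamycin at 0.796, 0.679 and 0.881, and combined array 2 with their arrays 3 at 0.625, 0.545 and 0.581. These are the values an exchange of the 2 numbers would give. Counts without a block do not use the numbers.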
